A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

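The series holds 6 two-colour spotted DNA arrays of Saccharomyces cerevisiae. Each array compared total RNA of the strain EKD-13, in which both copies of KNR4 are deleted, with RNA of its parent EC1118. Per the labels' protocols, precultures and fermentations were run at 28 °C in 1 L of the synthetic grape-must medium MS300 and sampled at 10 g of released CO2 (mid-exponential) or at 70 g (stationary). RNA was extracted with Trizol and cleaned on columns, and 5 µg was used for labelled cDNA, per the labels' protocols. There were 3 arrays per phase, and each one used separate fermentations of both strains, so the replicates are biological. The mutant was in Cy5 on arrays 1 and 3 and in Cy3 on array 2 of each phase. The vessel names in the labels show that mutant vessels F14 and F24 and wild-type vessels F22 and F21 served in both phases. On array 3 both vessels were the same in the 2 phases, on array 1 the mutant's and on array 2 the wild type's, so the array numbers pair the phases in part. Deviations of same-numbered arrays from their phase means correlated at 0.08, 0.21 and -0.05, and not every array correlated best with its own number. Both RNAs of an array came from the same fermentation set except on stationary array 2, per the labels.

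The authors deposited a table of log2 ratios per spot and array, made with R 2.9.2 and limma (limma version not stated) per the submitters' processing notes. The background correction, the normalization within arrays and the filter that left spots without a ratio are not given in the sources used here. Column medians were -0.004, -0.027 and -0.014 for mid-exponential and 0.019, 0.0 and 0.011 for stationary arrays. The authors also deposited, per the file headers, a limma table per phase of 6388 genes with a log2 fold change, a mean log2 intensity, a moderated t score, a p-value and an adjusted p-value, and for stationary phase a linear fold change. The authors' lists of changed genes held the rows of these tables with an adjusted p-value under 0.05, as checked on the files. Spots are printed as pairs for a gene, and the correlation between the pair ran from 0.713 to 0.870. The scale was checked against the authors' log2 fold changes: over bright genes the mean of the arrays had a slope of 1.18 (r = 0.985) and 1.24 (r = 0.972), closer to 1 than log10 or natural log values would give. On each array 98.6 to 100% of the genes called by the authors had the authors' sign, so the dye-swapped arrays had been turned before deposit. The sign as mutant over wild type rests on the dyes in the labels and on KNR4.

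Spots took their gene names through the printing plate wells. Genes in row E of plates 10 to 19 followed the authors' log2 fold changes poorly (r = 0.395 and 0.338, against 0.973 and 0.902 for the other rows), so 228 genes of those wells were left out because their names could not be relied on. Of the 6388 genes, 5849 were found in the reference annotation (R64) by locus tag and took its symbol. The other 539 were not and kept the name in the files. The chromosome of a gene was read from its systematic name. The reference gave the gene order along chromosome XII, for 346 of its 359 tested genes. A named well was found for 6156 genes, and 469 had no value on any array. The 128 spots named as not spotted were not used. Spots of a gene were averaged, and no values were scaled or filled in.

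Tests were run with limma 3.58.1 in R 4.3.3, and tables and plots with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. All 6 arrays entered a single limma model with a mean for each phase, which left 4 residual degrees of freedom, and empirical Bayes added 2.28 prior degrees. Genes with a ratio on at least 2 arrays of each phase were tested, 4289 in all, against a log2 ratio of 0 in each phase and for the difference between phases. Tests were two-sided with Benjamini-Hochberg adjustment over the genes, and a gene passed at an adjusted p under 0.05. An SD is over the arrays of a phase that measured the gene, and an SE is that of the limma model. Wild-type levels were not compared between phases, since each array held a single phase.

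Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, and with an estimated correlation beside it, over the 3020 genes with a ratio on all 6 arrays. The adjustment was over the lists of a contrast; lists with fewer than 5 such genes had counts only. Medians and counts of a list cover all its tested genes, often more than the list test did. That test took in 22 of 32 genes for cell cycle, 9 of 17 for glycogen and trehalose, 10 of 21 for cell wall integrity signalling and 7 of 12 for chitin. There were 32 lists: cell wall integrity signalling, Slt2-Rlm1 responsive cell wall genes, chitin, beta-glucan, cell wall mannoproteins, protein mannosylation, flocculins, DAN/TIR mannoproteins, seripauperins, haploid-cell markers, sporulating-cell markers, general stress response, chaperones, glycogen and trehalose, ribosome biogenesis, amino acid biosynthesis, methionine and sulphur, nitrogen catabolite repression, autophagy, phosphate, thiamine, iron, hexose transport, glycolysis, respiration, ergosterol, hypoxic genes, fatty acid and phospholipid synthesis, cell cycle, calcineurin-Crz1, multidrug resistance and cytosolic ribosomal proteins. No list with the preset correlation held its call with an estimated correlation. That second test also rests on the 4 residual degrees of freedom, so a lost call does not show that correlation undid it. For cell wall integrity in mid-exponential phase the estimate was -0.044, under the preset. Its camera p still went from 4.5e-04 to 0.021. The genes of near-identical families can share a spot's signal.

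The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. That rule took, per phase, KNR4 and its neighbours, the 12 largest rises and 12 largest falls among genes that passed with the same sign on 3 arrays, and the 3 members of each list with the smallest p. For the difference between phases it took the largest differences among genes that passed. The grouping of genes by chromosome was made after their values were seen.

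The programs were tested on simulated data: 20 simulations of 4289 genes with 200 changed. A simulated gene had the same spread on every array and varied independently of the other genes. For mid-exponential phase 36.9% of the 2-fold and 75.2% of the 4-fold changes were recovered, and for stationary phase 31.9 and 67.7%; 5.04 and 4.87% of the calls were false. A simulated list of 30 genes raised by 0.5 was called in 20 of 20 runs, and an unmoved list in 1. The real arrays differed in spread, with array weights from 0.27 to 3.12. Estimated correlations within the real lists ran from -0.090 for chitin to 0.561 for ergosterol synthesis. The simulation held neither feature, so its shares of false calls need not hold for the real data.

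Alternatives covered centring and scaling of the arrays, a dye term, each phase alone, shared vessels as a replicate block, a robust trended prior, single spots, removal of dim genes, genes on all arrays, other thresholds, the authors' tables and omission of each array. Further ones were added after seeing the data: a prior that follows intensity, array weights, both spots kept, list tests over all tested genes and with the vessel block, and fits without the arrays with the mutant in Cy3 or without chromosome XII.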

Results

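The series compared the transcripts of a wine yeast with those of a derivative that lacks KNR4 during alcoholic fermentation. EC1118 is an industrial Saccharomyces cerevisiae wine strain, and EKD-13 was built from it by deleting both copies of KNR4. KNR4, also named SMI1 (YGR229C), encodes a protein tied to the control of cell wall synthesis and to the Slt2 cell wall integrity pathway. Each of 6 spotted two-colour arrays held RNA from a mutant and a wild-type fermentation taken at the same stage. There were 3 arrays for mid-exponential phase, at 10 g of released CO2, and 3 for stationary phase, at 70 g. The mutant was in Cy5 on arrays 1 and 3 of each phase and in Cy3 on array 2. The array table had 15488 spots, of which 53.1 to 85.6% carried a log2 ratio on a given array. Stationary arrays were the sparser ones: of the dim genes, those in the lowest quartile of intensity, 11.7 to 23% had a ratio there, against 54.6 to 76.3% on the mid-exponential arrays. The small number of arrays limits the precision of every value.

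The deleted gene was examined first, because it checks the labels and the direction of the ratios. All values are log2 of mutant over wild type; this direction rests on the dyes in the labels, on the turned sign of the dye-swapped arrays, and on the low value of KNR4 itself. In the authors' deposited table KNR4 (SMI1) stood at -1.89 in mid-exponential phase, with an adjusted p of 2.7e-04. The authors' deposited table gave KNR4 -1.74 in stationary phase, with an adjusted p of 2.5e-04. With the gene deleted the mutant's channel can hold background only, so these values give the direction and no fold. KNR4 carried a ratio on 1 array only, mid-exponential array 3, where it was -4.51; it had none on the other 5, so the refit could not test it. The authors' deposited table listed DIE2 at -0.13 and -0.06, the overlapping open reading frame YGR228W at -0.03 and -0.07, and BNS1 at 0.28 and -0.25 in mid-exponential and stationary phase. None of these 3 passed in the authors' deposited table, with adjusted p from 0.13 to 0.96. The ratios per array of these neighbours on chromosome VII were too scattered to exclude a smaller fall. DIE2 was below 0 on 4 of 5 arrays, at -1.41 to 0.01, YGR228W had 3 ratios, from -0.94 to 3.33, and BNS1 had 6, from -0.67 to 2.48.

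In mid-exponential phase the strongest rise in the mutant was in INO1, which encodes inositol-3-phosphate synthase, the first step of inositol synthesis. It rose by 2.76 ± 0.30 (SD, n = 3) on the log2 scale, 6.79-fold, with a limma adjusted p of 0.025. MID2, a plasma membrane sensor of the cell wall integrity pathway, rose by 2.51 ± 0.36 (n = 3), 5.68-fold (adjusted p = 0.041). PUN1, a plasma membrane protein, rose by 1.80 ± 0.19 and IMD1, of the IMP dehydrogenase family, by 1.60 ± 0.05, while NYV1, LCL2 and VID22 rose by 1.56, 1.42 and 1.41. JLP1, a sulphonate dioxygenase, fell by 3.86 ± 0.47 (n = 3), 14.6-fold, and CPA1, the small subunit of the arginine-specific carbamoyl phosphate synthetase, fell by 1.42 ± 0.21. These 9 genes, 7 higher and 2 lower, were the ones that passed among 4289 tested, and 8 of the 9 were also called with the same sign in the authors' deposited table. The sizes there were smaller: the authors' deposited table listed INO1 at 2.16, MID2 at 1.33, PUN1 at 1.12, IMD1 at 1.29, NYV1 at 0.87, LCL2 at 0.66, VID22, the one not called, at 0.47, JLP1 at -1.31 and CPA1 at -1.09. MID2, PUN1, NYV1, LCL2, VID22 and JLP1 lie on chromosome XII, whose 359 tested genes as a group stood higher in the mutant, at a mean of array medians of 0.68 ± 0.10 (n = 3). With a dye term in the model INO1 alone passed, at 2.83 (adjusted p = 0.046). The other 8 had an adjusted p of 0.098, with sizes that moved little, such as 2.51 for MID2 and -3.93 for JLP1. IMD1 has near-identical relatives that can share its spot, among them IMD3 on chromosome XII, and is uncertain on its own.

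Of the cell wall lists 3 stood higher in the mutant. The Slt2-Rlm1 responsive cell wall genes had a median of 0.68 over 21 tested members (limma camera, adjusted p = 1.5e-04; adjusted p = 0.301 with an estimated correlation). None of them passed over all genes and 3 rose when adjusted over the list alone; the authors' deposited table had 13 of 29 higher and 2 lower. The list's lead members were SRL3 at 1.66 ± 0.25, the cell wall protein gene NCW2 at 1.34 ± 0.32 on chromosome XII, and the kinase gene KDX1 at 2.37 ± 0.92 (n = 3 each), with adjusted p of 0.060, 0.091 and 0.107. The cell wall integrity signalling list had a median of 0.46 over 21 members, of which MID2 rose over all genes and 5 rose adjusted over the list alone (camera adjusted p = 0.0027; adjusted p = 0.190 with an estimated correlation). Its next members were the phosphatase gene PTP2 at 1.26 ± 0.23 and SWI6, on chromosome XII, at 1.16 ± 0.30 (n = 3 each), neither past the threshold. The list test covered 10 of these 21 members. With 4 of the 21 on chromosome XII, the cell wall integrity list was not called once that chromosome's genes were left out (adjusted p = 0.190). Chitin synthesis and remodelling had a median of 0.43 over 12 members, none past either threshold (camera adjusted p = 0.021; adjusted p = 0.288 with an estimated correlation). CHS3, the main chitin synthase, stood at 0.65 ± 0.14 and the chitin cross-linker CRH1 at 0.79 ± 0.50 (n = 3 each).

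The seripauperins, the PAU family of small mannoproteins known from anaerobic growth, were the most uniform group. Their median was 0.79 over 24 tested genes, 23 of them above 0 (camera adjusted p = 5.3e-15; adjusted p = 0.190 with an estimated correlation). None passed over all genes, 21 rose when adjusted over the list alone, and the authors' deposited table also had 21 of 24 higher. PAU6 stood at 1.14 ± 0.24, PAU20 at 1.11 ± 0.23 and PAU24 at 1.04 ± 0.19 (n = 3 each). The copies are nearly identical and can bind the same RNA, so their number is not a number of independent genes; 4 of the 24 lie on chromosome XII. Thiamine metabolism had a median of 0.27 over 23 genes, with none past the threshold over all genes and 2 risen when adjusted over the list alone (camera adjusted p = 0.0045; adjusted p = 0.190 with an estimated correlation). THI22 stood at 0.77 ± 0.03, the pyruvate decarboxylase gene PDC5, on chromosome XII, at 0.84 ± 0.05, and THI6 at 0.66 ± 0.22 (n = 3 each).

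The lists of respiration, amino acid biosynthesis and the general stress response were called as lower in the mutant in this phase, the second without the same sign on each array. Respiration and the tricarboxylic acid cycle had a median of -0.35 over 47 genes, none past either threshold (camera adjusted p = 1.5e-06; adjusted p = 0.190 with an estimated correlation), and the authors' deposited table had 20 of 62 lower and 3 higher. COX13 stood at -1.42 ± 0.83, LSC2 at -1.02 ± 0.30 and COX5A at -0.99 ± 0.64 (n = 3 each). Amino acid biosynthesis had a median of -0.13 over 57 genes, with CPA1 lower over all genes and 5 fallen when adjusted over the list alone (camera adjusted p = 0.0027; adjusted p = 0.351 with an estimated correlation). Its medians were -0.21 and -0.18 on arrays 1 and 2 and 0.06 on array 3. Beside CPA1, its members with the smallest p were ARG1 at -1.45 ± 0.26 and ARG4 at -1.16 ± 0.36 (n = 3 each), neither past the threshold (adjusted p = 0.107 for both). The general stress response list had a median of -0.25 over 30 genes, none past over all genes and 2 fallen when adjusted over the list alone (camera adjusted p = 0.021; adjusted p = 0.834 with an estimated correlation). The small heat shock gene HSP26 was at -3.73 ± 1.05 (n = 3, adjusted p = 0.091), and the authors' deposited table had 13 of the 39 stress genes lower and none higher. This call did not pass with a dye term in the model (adjusted p = 0.209).

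Ergosterol synthesis had a median of -0.45 over 25 genes, none past either threshold (camera adjusted p = 0.021; adjusted p = 0.834 with an estimated correlation). Its array medians were 0.21, -0.62 and -0.90, and the call was not passed without mid-exponential replicate 2 (adjusted p = 0.183) or 3 (0.187). Of its members with the smallest p, HMG2, on chromosome XII, stood higher, at 0.53 ± 0.22. ERG4 stood at -0.43 ± 0.07 and IDI1, the isopentenyl diphosphate isomerase gene, at -0.87 ± 0.58 (n = 3 each). Cell cycle and budding had a median of -0.25 over 32 genes, none past either threshold (camera adjusted p = 0.021; adjusted p = 0.744 with an estimated correlation), and was not called with a dye term (adjusted p = 0.092), without mid-exponential replicate 2 (0.107) or without stationary replicate 2 (0.055). The chitin list likewise was not called without mid-exponential replicate 1 (adjusted p = 0.053). Over all tested genes neither ergosterol synthesis (adjusted p = 0.060) nor cell cycle and budding (0.176) was called. Of the cell cycle members with the smallest p, HTB1 stood at -0.86 ± 0.33 (n = 3). MCM5 at 0.78 ± 0.31 and CTS1 at 0.73 ± 0.48 (n = 3 each), both on chromosome XII, stood higher.

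The remaining lists were not called in mid-exponential phase over the genes on all arrays, with camera adjusted p from 0.056 for glycogen and trehalose metabolism, 0.057 for protein-folding chaperones, 0.061 for calcineurin-Crz1 responsive genes and 0.065 for beta-glucan synthesis up to 0.904. In beta-glucan synthesis none of 21 passed over all genes and 4 rose adjusted over the list alone; KRE6, needed for beta-1,6-glucan, stood at 0.96 ± 0.26 (n = 3). Cell wall mannoproteins (adjusted p = 0.215), protein mannosylation (0.373), the anaerobic DAN/TIR mannoproteins (0.373), hypoxic genes (0.702), fatty acid and phospholipid synthesis (0.748), nitrogen catabolite repressed genes (0.220), methionine and sulphur assimilation (0.648), ribosome biogenesis (0.431) and glycolysis (0.374) were among them. Autophagy, the phosphate and iron regulons, hexose transport, multidrug resistance, the cytosolic ribosomal proteins and sporulating-cell markers all had 0.904. Over all tested genes glycogen and trehalose metabolism was called as lower (adjusted p = 0.0043; adjusted p = 0.744 with an estimated correlation). On the t scores of the authors' deposited table it was called too (adjusted p = 4.7e-04), as were chaperones as lower (0.0040), and cell wall mannoproteins (0.0095) and calcineurin-Crz1 responsive genes (0.014) as higher. With an estimated correlation in the refit none of these 4 was called (adjusted p = 0.744, and 0.834 for chaperones). Flocculins and haploid-cell markers had too few genes on all arrays for the list test; the authors' deposited table called none of 5 flocculins, 32 haploid-cell and 38 sporulating-cell markers in either phase.

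The number of single genes called was small and depended on the fit. Arrays brought to one spread gave 199 genes, 132 higher and 67 lower, against 7 and 2 as deposited, and the authors' deposited table has 658, 362 higher and 296 lower. In limma, omission of mid-exponential replicate 1, 2 or 3 or of stationary replicate 1 left 0 genes, with 402, 291, 310 and 431 at an unadjusted p under 0.05 against 570 with all arrays; omission of stationary replicate 3 left 2, and of stationary replicate 2 left 15.

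In stationary phase the mutant had more HXT1, a low-affinity glucose transporter, and less INO1. HXT1 rose by 2.22 ± 0.14 (n = 3), 4.66-fold, and INO1 fell by 2.80 ± 0.33 (n = 3), 6.99-fold, each with a limma adjusted p of 0.0046. AZR1, a plasma membrane drug transporter, fell by 3.60 ± 0.31 and RNR3, a damage-inducible ribonucleotide reductase subunit, fell by 2.95 ± 0.11 (n = 3 each; adjusted p = 0.0019 for both). The chaperone gene SSA3 fell by 4.83 ± 2.06 and SIP18, a hydrophilin gene of the stress response, fell by 4.30 ± 2.38 (n = 3 each), with array values as far apart as -1.71 and -6.40 for SIP18. The authors' deposited table called these 6 genes with smaller values, HXT1 at 2.11, INO1 at -2.28, AZR1 at -1.38, RNR3 at -1.12, SSA3 at -1.63 and SIP18 at -3.02. Of 4289 tested genes 204 passed, 128 higher and 76 lower, of which 80 and 59 had the same sign on 3 arrays.

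The other large rises were RAX2 at 3.32 ± 1.22, involved in bud site selection, the oligopeptide transporter gene OPT2 at 3.03 ± 1.32, the fatty acid elongase gene ELO3 at 2.64 ± 0.61, YLR111W at 2.34 ± 0.66, ARL3 at 2.32 ± 1.01, LCL2 at 2.31 ± 0.20, ATF2, an alcohol acetyltransferase gene, at 2.21 ± 1.07, MCM5, a subunit of the replicative helicase, at 2.14 ± 0.25, NYV1 at 2.11 ± 0.19, PUS5 at 2.08 ± 0.54 and KTD1 at 2.06 ± 0.78 (n = 3 each). RAX2, ELO3, YLR111W, LCL2, MCM5, NYV1 and PUS5 lie on chromosome XII. Among the falls were YMR187C at -2.95 ± 0.68, the co-chaperone gene CNS1 at -2.71 ± 0.64, SPG1 at -2.38 ± 0.83, LYS20, a homocitrate synthase gene, at -2.10 ± 0.95, FMP48 at -2.04 ± 0.53, ICS3 at -2.03 ± 0.61 and SIP4 at -1.84 ± 0.50 (n = 3 each). In the authors' deposited table, 86 of the 204 were called with the same sign and 201 had the same sign; RAX2, YLR111W, ARL3, PUS5, KTD1, CNS1, LYS20 and ICS3 were among those it did not call. Sizes differed more than signs, and were compared after the values were seen: the log2 value in the authors' deposited table was a median of 0.277 of the refit's over the 204 genes, and 0.560 over the 9 of mid-exponential phase. ELO3, for instance, stood at 0.65 and RAX2 at 0.41 in the authors' deposited table. The gap was wider for ARL3 at 0.20 and KTD1 at 0.15 there, and CNS1 showed next to no change, at -0.07 (adjusted p = 0.84). The sizes printed for single genes here are therefore uncertain.

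The stress and chaperone lists were called as lower in the stationary mutant, though not lower alike on the 3 arrays. Protein-folding chaperones had a median of -0.35 over 30 genes, of which 3 fell over all genes and 3 adjusted over the list alone (camera adjusted p = 0.0024; adjusted p = 0.668 with an estimated correlation). The chaperone medians were -0.46 and -0.59 on stationary arrays 1 and 3 and -0.02 on array 2. Beside SSA3 the genes that fell were ERO1, needed for disulphide formation in the endoplasmic reticulum, at -1.81 ± 0.66 and HSP31 at -1.66 ± 0.69 (n = 3 each). The general stress response had a median of -0.76 over 30 genes, with 4 fallen over all genes and 4 adjusted over the list alone (camera adjusted p = 0.0024; adjusted p = 0.668 with an estimated correlation). TPS2, of trehalose synthesis, fell by 1.19 ± 0.16 (n = 2), and the glycogen debranching gene GDB1 by 1.15 ± 0.44 (n = 3). The stress list's medians were -1.09 and -0.83 on stationary arrays 1 and 3 but 0.31 on array 2, the one with the mutant in Cy3. Per the labels this was also the only array whose mutant and wild-type RNA came from different fermentation sets. The authors' deposited table called neither TPS2 (-0.25, adjusted p = 0.194) nor GDB1 (-0.36, adjusted p = 0.095). Multidrug resistance had a median of -0.38 over 23 genes, with AZR1 and the reductase gene GRE2, which fell by 2.32 ± 0.02 (n = 2), past the threshold over all genes and 3 fallen adjusted over the list alone (camera adjusted p = 0.017; adjusted p = 0.514 with an estimated correlation). GRE2 stood at -0.48 in the authors' deposited table, where it was not called (adjusted p = 0.185).

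Respiration and the tricarboxylic acid cycle were again lower, with a median of -0.30 over 47 genes and none past either threshold (camera adjusted p = 0.0024; adjusted p = 0.668 with an estimated correlation). MLS1, malate synthase of the glyoxylate cycle, stood at -1.60 ± 0.84, ACS1 at -1.54 ± 1.11 and MDH1 at -0.66 ± 0.19 (n = 3 each). Thiamine metabolism was again higher, with a median of 0.38 over 23 genes, of which THI72, a thiamine transporter gene, rose by 1.35 ± 0.11 (n = 3) over all genes and 2 rose adjusted over the list alone (camera adjusted p = 0.0024; adjusted p = 0.514 with an estimated correlation). The cytosolic ribosomal proteins had a median of 0.12 over 122 genes, with 4 risen over all genes and 4 adjusted over the list alone (camera adjusted p = 0.0024; adjusted p = 0.755 with an estimated correlation). The medians were 0.39 and 0.07 on stationary arrays 1 and 3 and -0.01 on array 2. RPS30B rose by 1.26 ± 0.37, RPS31 by 1.18 ± 0.20 and RPL26A by 0.97 ± 0.27 (n = 3 each); RPS31 and RPL26A lie on chromosome XII, as do 16 of the 122.

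The cell wall lists were not called in stationary phase by camera over the genes on all arrays, though single members passed. FKS1, a catalytic subunit of beta-1,3-glucan synthase on chromosome XII, rose by 1.53 ± 0.60 and PIR1, a cell wall protein gene, rose by 1.55 ± 0.59 (n = 3 each). WSC2, a cell wall stress sensor, rose by 2.29 ± 0.48, KDX1 by 3.92 ± 0.60 and SWI4 by 1.81 ± 0.23 on the 2 arrays that measured them. The authors' deposited table called none of these 3, with WSC2 at 0.40 (adjusted p = 0.078), KDX1 at 0.28 (0.142) and SWI4 at 0.08 (0.783). In the cell wall integrity list 5 of 21 rose over all genes and 6 adjusted over the list alone (camera adjusted p = 0.159; adjusted p = 0.668 with an estimated correlation). The Slt2-Rlm1 responsive list had 2 of 21 risen over all genes and 3 adjusted over the list alone (camera adjusted p = 0.146; adjusted p = 0.668 with an estimated correlation). Beta-glucan synthesis had 3 of 21 risen over all genes, SCW4 and, both on chromosome XII, FKS1 and ACF2. It had 6 risen and 2 fallen adjusted over the list alone (camera adjusted p = 0.101, and adjusted p = 0.668 with an estimated correlation). Over all tested genes the cell wall integrity list was called as higher (adjusted p = 0.025) and the Slt2-Rlm1 list was not (0.072). On the t scores of the authors' deposited table the Slt2-Rlm1 list was called as higher (adjusted p = 0.011) and the cell wall integrity list, with 1 of 28 genes risen, was not (0.137). The PAU family, at a median of -0.13, had none past either threshold (camera adjusted p = 0.488; adjusted p = 0.884 with an estimated correlation).

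Of the other lists none was called in stationary phase by camera over the genes on all arrays. Glycogen and trehalose metabolism and glycolysis came closest (camera adjusted p = 0.057 for both; adjusted p = 0.668 with an estimated correlation for both), with 2 of 17 and 1 of 27 fallen over all genes and, adjusted over the list alone, 1 risen and 4 fallen in the first and 2 risen and 1 fallen in the second. GPP1, a glycerol-3-phosphatase gene, fell by 1.51 ± 0.61 (n = 3). In hexose transport HXT1 and HXT6, the latter at 0.95 ± 0.30 and nearly identical to HXT7, rose and HXT5 fell by 1.54 ± 0.28 (n = 3 each), while 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.406). Fatty acid and phospholipid synthesis had 2 risen and 2 fallen of 28 by either count (camera adjusted p = 0.234), the falls being INO1 and OPI3, a phospholipid methyltransferase gene, at -1.44 ± 0.51 (n = 3). OPI3 was not called in the authors' deposited table (-0.46, adjusted p = 0.075). Nitrogen catabolite repressed genes had OPT2 risen and the arginine permease gene CAN1 fallen by 1.08 ± 0.33 (n = 3), with 1 risen and 2 fallen of 26 adjusted over the list alone (camera adjusted p = 0.178). Camera adjusted p was 0.241 for chitin synthesis, 0.251 for ergosterol synthesis, 0.339 for cell wall mannoproteins, autophagy and sporulating-cell markers, 0.406 for ribosome biogenesis and 0.698 for hypoxic genes. It was 0.779 for methionine and sulphur assimilation, 0.861 for amino acid biosynthesis, 0.908 for protein mannosylation and calcineurin-Crz1 responsive genes, 0.920 for the iron regulon and 0.971 for the DAN/TIR mannoproteins. Over all tested genes glycogen and trehalose metabolism (adjusted p = 0.0069) and sporulating-cell markers (0.025) were called as lower and cell cycle and budding (0.0039) as higher. None of these 3 was called with an estimated correlation (adjusted p = 0.668, 0.697 and 0.884). On the t scores of the authors' deposited table glycogen and trehalose metabolism (adjusted p = 0.030), glycolysis (0.021) and nitrogen catabolite repressed genes (0.012) were called as lower, and hexose transport (0.011) and cell cycle and budding (0.014) as higher; with an estimated correlation in the refit these had adjusted p = 0.668, and 0.884 for cell cycle and budding.

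The stationary counts depended on single arrays and on the residual variance shared with the other phase. The number of genes was 6 to 15 without any 1 of the mid-exponential arrays, 11 without stationary replicate 1, 355 without replicate 2 and 33 without replicate 3; of the 6 lists only thiamine metabolism (adjusted p = 0.022) passed without stationary replicate 1. A dye term left 72, without SIP18 (adjusted p = 0.055), ARL3 (0.073), KTD1 (0.052) and ICS3 (0.052). With arrays brought to one spread 16 genes passed, 8 higher and 8 lower, against 128 and 76, and with each phase fitted alone in limma 0 passed, with 553 at an unadjusted p under 0.05; the authors' deposited table has 267, 130 higher and 137 lower.

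**Figure D1:**
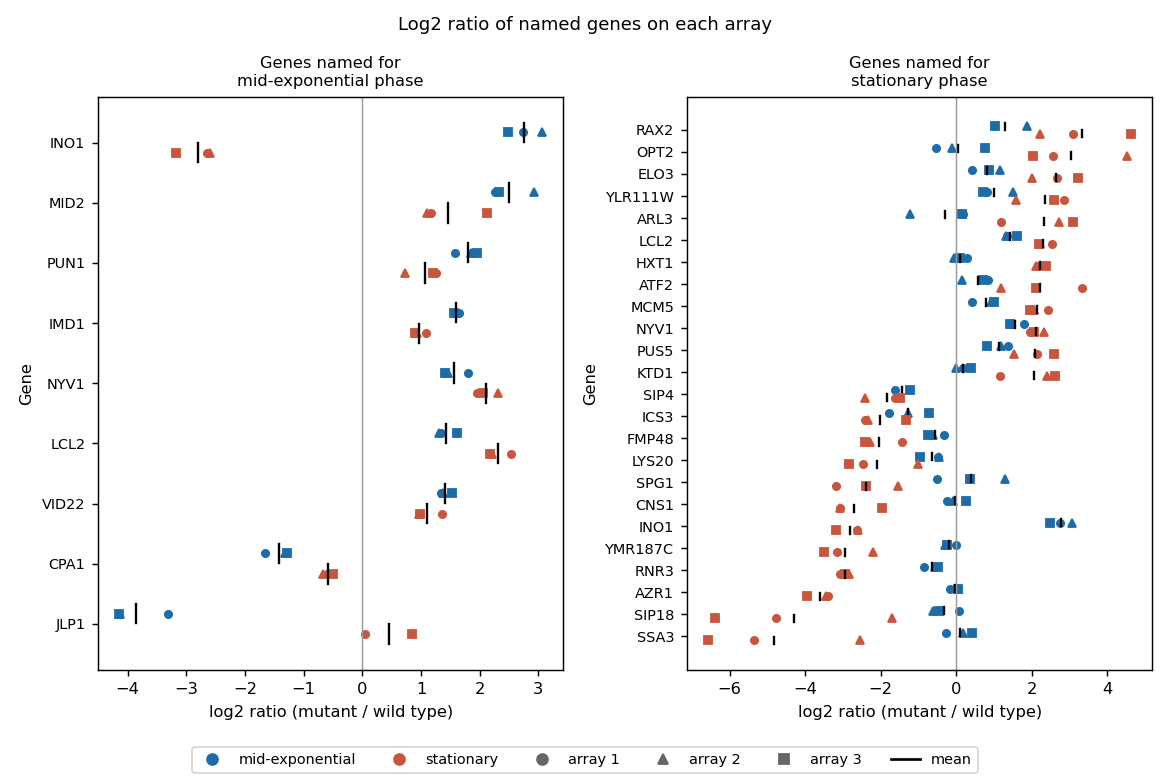
Log2 ratio of mutant over wild type for named genes on each of the 6 arrays; points are single arrays, by phase and array number, and short black lines the mean of a phase. INO1 lay between 2.48 and 3.07 on the mid-exponential arrays and between -3.18 and -2.59 on the stationary ones.

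The difference between phases was tested in the same limma fit, as stationary minus mid-exponential. INO1 was higher in the mutant in mid-exponential phase and lower in stationary phase, a difference of -5.57 (SE 0.28; adjusted p = 0.0028). AZR1 and RNR3 differed by -3.57 (SE 0.24; adjusted p = 0.0096) and -2.32 (SE 0.22; adjusted p = 0.042). HXT1 differed by 2.13 (SE 0.22; adjusted p = 0.043) and VHR2, a paralogue of the biotin-response regulator gene VHR1, by 3.23 (SE 0.26; adjusted p = 0.042) with 2 stationary arrays. These 5 genes passed among 4289, and 548 had an unadjusted p under 0.05. For VHR2 the authors' deposited table listed 0.11 in stationary phase with an adjusted p of 0.53.

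Among the gene lists, the PAU family had a median difference of -0.91, with none of 24 past the threshold over all genes and 15 lower adjusted over the list alone (camera adjusted p = 6.5e-12; adjusted p = 0.521 with an estimated correlation). Multidrug resistance had a median difference of -0.27 with AZR1 past the threshold over all genes and 3 adjusted over the list alone (camera adjusted p = 0.026; adjusted p = 0.521 with an estimated correlation). Cell cycle and budding differed by a median of 0.53, with none of 32 past the threshold over all genes and 6 adjusted over the list alone (camera adjusted p = 0.0046; adjusted p = 0.881 with an estimated correlation). The cytosolic ribosomal proteins differed by 0.15 (camera adjusted p = 0.0046; adjusted p = 0.881 with an estimated correlation) and amino acid biosynthesis by 0.16 (camera adjusted p = 0.042; adjusted p = 0.881 with an estimated correlation), each with none past either threshold. Over all tested genes these last 2 lists were not called (adjusted p = 0.093 for both), while fatty acid and phospholipid synthesis (0.025) and sporulating-cell markers (0.029) were called as lower. Neither of the latter was called by camera over the genes on all arrays (adjusted p = 0.410 and 0.420; adjusted p = 0.881 for both with an estimated correlation). With the shared vessels as fixed block terms, which left fewer residual degrees of freedom, 1 gene passed, INO1 (adjusted p = 0.040). Of the 5 lists 4 were called, without amino acid biosynthesis (adjusted p = 0.074). With a dye term 2 passed, INO1 (adjusted p = 0.0066) and AZR1 (0.035). Omission of single arrays gave 1 or 2 genes except for 21 without stationary replicate 2.

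Across the 4289 genes, the mean ratios of the phases had a Pearson's r of 0.303 and a Spearman's rho of 0.289; genes are not independent replicates, so no p is attached. In the authors' deposited table, 58 genes rose in both phases where 7.37 would be met by chance from independent lists, and the authors' deposited table had 52 genes that fell in both against 6.35. Outside chromosome XII the authors' deposited table had 11 genes that rose in both against 1.51 and 52 that fell in both against 6.88. No p is attached to these overlaps either, since neither the genes nor all of the cultures were independent. The 3 genes that the authors' deposited table called with opposite signs were INO1, PIR1 and RTA1. In the refit MID2, PUN1, IMD1, NYV1, LCL2 and VID22 rose in both phases and INO1 changed in opposite directions. Some fermentation vessels were sampled in both phases, so part of the overlap may come from the shared cultures. Without the genes of chromosome XII the r was 0.181.

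**Figure D2:**
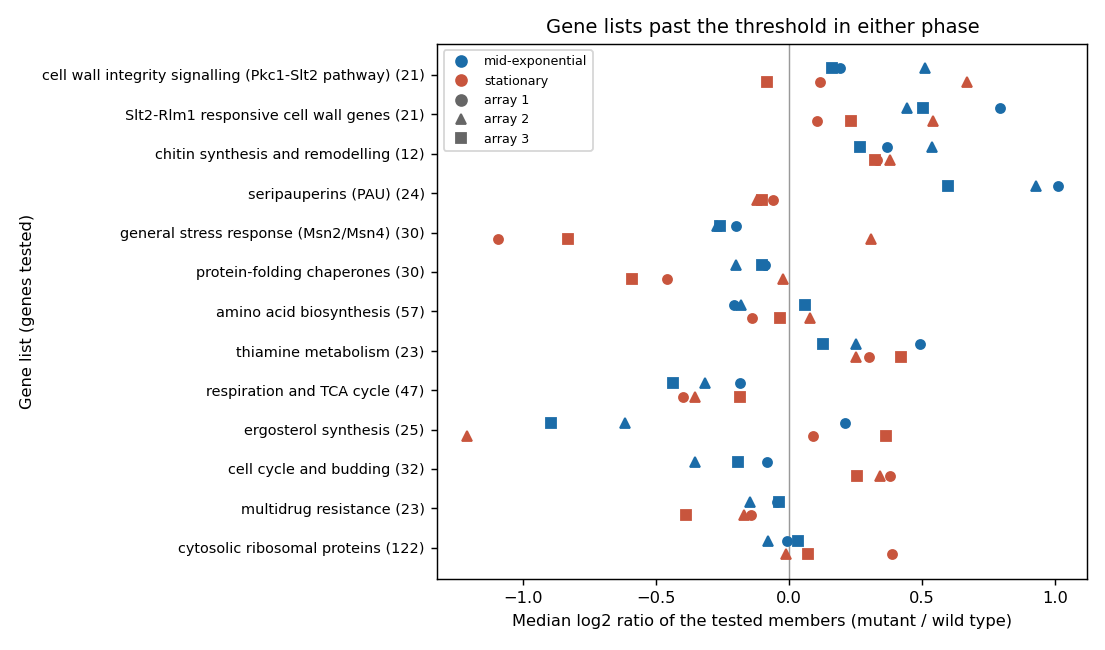
Median log2 ratio of mutant over wild type of the tested members of each gene list called in either phase, one point per array, with the number of genes in brackets. The PAU family lay between 0.60 and 1.01 on the mid-exponential arrays and between -0.12 and -0.06 on the stationary ones.

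The values by chromosome were compared after many of the rising genes were seen to lie on one of them. The 359 tested genes of chromosome XII had array medians of 0.62, 0.79 and 0.63 in mid-exponential phase, a mean of 0.68 ± 0.10 (SD, n = 3), and of 0.63, 0.50 and 0.97 in stationary phase, a mean of 0.70 ± 0.25 (n = 3). On each of the 6 arrays this was the highest median of the 16 chromosomes; the medians of the others lay between -0.37 and 0.27. On single arrays 75.1 to 92.4% of chromosome XII genes were above 0, against 42.9 to 50.0% of the genes elsewhere. The shift against the other chromosomes was 0.73 ± 0.16 (SD, n = 6). No p is given for it, since the chromosome was picked for its values and some vessels were shared. In the authors' deposited table the medians of chromosome XII genes were 0.34 and 0.20 in the phases, over all 551 of them rather than the 359 tested. In the authors' deposited table, 232 of the 362 genes that rose in mid-exponential phase and 62 of the 130 that rose in stationary phase lie on chromosome XII, while 3 and 0 of its genes fell. In the refit 5 of the 7 mid-exponential rises and 58 of the 128 stationary rises lie there.

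**Figure D3:**
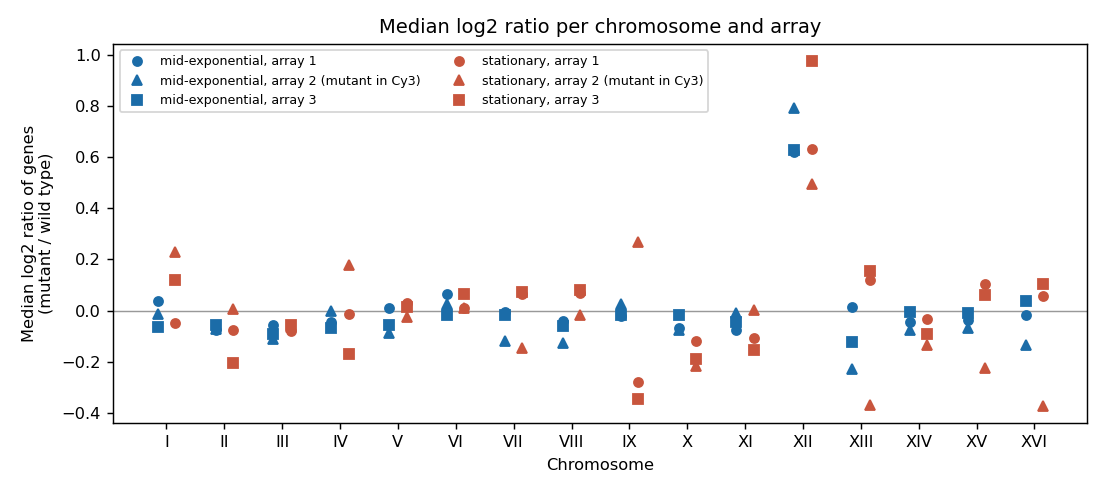
Median log2 ratio of mutant over wild type of the genes of each nuclear chromosome on each of the 6 arrays. Chromosome XII lay between 0.50 and 0.97, and the other 15 between -0.37 and 0.27.

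**Figure D4:**
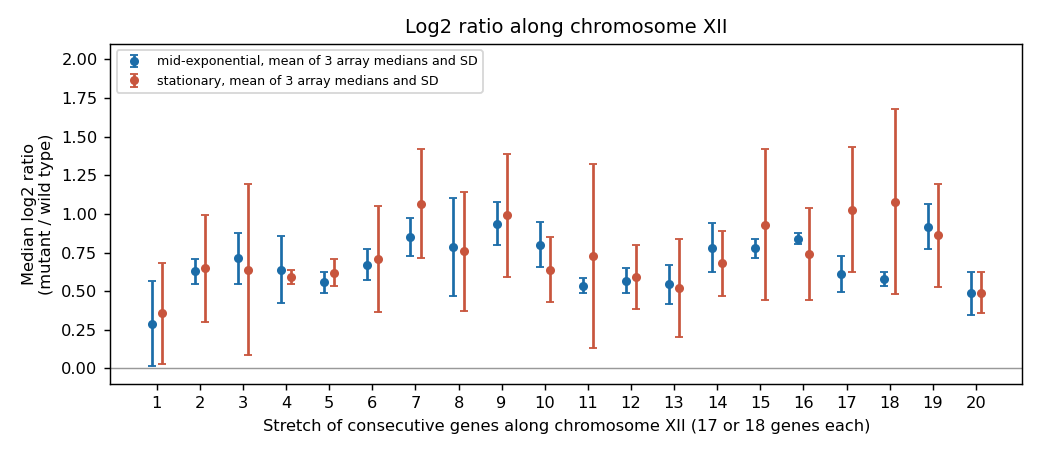
Log2 ratio along chromosome XII in 20 stretches of consecutive genes, with the mean and SD of the 3 array medians of each phase. The means over the 6 arrays ran from 0.32 in the first stretch to 0.96.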

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

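The dye test of INO1 was chosen after the result was seen; the list of genes that respond to Ino2 and Ino4 was written before its test. Single genes and lists are given here because the mutant's effect differed between the phases in the test of the difference itself.

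INO1 differed by -5.57 on the log2 scale between stationary and mid-exponential phase, higher in the mutant on each of 3 mid-exponential arrays and lower on each of 3 stationary ones. Dye bias is argued against, since the lowest mid-exponential value was 2.48 and the arrays of both dye orientations had the same sign. If the activators Ino2 and Ino4, which drive INO1 and other phospholipid genes, were the source, their other target genes would move along; 17 tested genes other than INO1 had a median difference of -0.43, with 15 of them lower. That is below the central range, -0.33 to 0.28, of 10000 random lists matched on intensity, though none of the 17 passed. The random lists were drawn gene by gene and do not reproduce correlation among co-regulated genes, so this range may be too narrow. The fatty acid and phospholipid list, which includes INO1 and many of these genes, was not called for the difference by camera over the genes on all arrays (adjusted p = 0.410). Over all tested genes it was called as lower (0.025). The median of the 17 was -0.42 in stationary phase, which was not set against random lists, and -0.06 in mid-exponential phase. A shared shift may contribute to the stationary fall of INO1 but is not established, and its mid-exponential rise stays open.

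The other genes that passed the test of the difference were AZR1 at -3.57, RNR3 at -2.32, HXT1 at 2.13 and VHR2 at 3.23, the last with 2 stationary arrays. With shared vessels as fixed block terms 1 of the 5, INO1, kept its call (adjusted p = 0.040), and the other 4 had adjusted p from 0.257 to 0.492. Those terms left fewer residual degrees of freedom, so the lost calls need not come from the shared vessels. With a dye term INO1 and AZR1 passed. For the count of 5 the splits of the 6 arrays are too few for a share under 0.05; 1 of the 10, the real one, gave 5 genes and the highest other gave 0. Among the lists, the median difference was -0.91 for the seripauperins, 0.16 for amino acid biosynthesis, 0.53 for cell cycle and budding, -0.27 for multidrug resistance and 0.15 for the cytosolic ribosomal proteins, and no list's call held with an estimated correlation.

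The 128 spots named as not spotted are given here because 30.1% of their values over the 6 arrays held a ratio. What share a spot without DNA would give under the unstated background correction and filter is not known, so no test is attached. On the mid-exponential arrays the share was 28.1, 21.1 and 31.2%, where 56.5, 54.6 and 76.3% of the dim genes had a ratio. On the stationary arrays it was 35.9, 35.9 and 28.1%, where 12.8, 11.7 and 23% of the dim genes had one. The former are shares of spots and the latter of genes with a ratio at any of their spots, so they are not compared. The source of these ratios was not tested. The median absolute log2 ratio at these spots was 0.85.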

How the results depend on the processing

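Fits with an intensity prior, array weights, both spots kept, without Cy3 arrays or without chromosome XII, and list tests over all tested genes or with the vessel block, were chosen after seeing the data. Counts are of genes past the threshold in mid-exponential phase, stationary phase and for the difference, against 9, 204 and 5.

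The fit shares 1 residual variance per gene between the phases. Array weights were 1.04 to 3.12 for mid-exponential and 0.27 to 1.00 for stationary arrays. The shared variance can thus make mid-exponential p-values too large and stationary ones too small. Genes at an unadjusted p under 0.05 were 570 and 1029 in the shared fit. So 9 and 204 do not compare the phases. Apart from this, where a count moved by over 1.5 times, the cause was not tested unless fewer genes or arrays give it. Scaling to one spread gave 199 and 16; a dye term gave 1, 72 and 2; each phase alone gave 0 and 0, with 1228 and 553 genes at an unadjusted p under 0.05. The robust trended prior gave 1, 1 and 1, single spots 335 in stationary phase, and an adjusted p under 0.01 left 0, 7 and 2. The authors' tables have 658 in mid-exponential phase. Array weights gave 423 and 57. Each phase alone gave 248 and 10 with a prior that follows intensity, and 621 and 6 with both spots kept. Without the arrays with the mutant in Cy3 the counts were 0, 87 and 0, with 399 and 497 genes at an unadjusted p under 0.05 for the zeros, and without chromosome XII 2 and 113 in the phases.

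Leave-one-out counts ran from 0 to 15 in mid-exponential phase, from 6 to 355 in stationary phase and from 1 to 21 for the difference. The lowest counts came without mid-exponential replicate 1, 2 or 3 or stationary replicate 1, and the highest each time without stationary replicate 2, whose ratios correlated across genes at -0.006 with stationary array 3 and 0.16 with array 1, against 0.56 between those. The sign patterns of 3 arrays are too few for a share under 0.05: in each phase 1 of the 4, the real one, gave as many genes, 9 with a highest other of 0 and 204 with a highest other of 7.

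In the phases the shared vessels entered as a correlation between the arrays of a block, estimated at 0.043, and the counts were 9 and 204. For the difference the blocks entered as fixed terms, which left fewer residual degrees of freedom, and the count was 1. The lower count can come from those lost degrees of freedom, so it does not show that shared vessels undid the calls. For the difference INO1 passed and AZR1, RNR3, HXT1, VHR2 and the amino acid biosynthesis list did not; the block changed no other call among the largest changes, and shared 203 of the 204 stationary genes and all 9 mid-exponential ones. Lists in a single phase were not tested with it.

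The correlation between the phases, 0.303, was 0.366 without the dim genes, 0.361 over genes on all arrays, 0.363 in the authors' tables, 0.385 without the Cy3 arrays, 0.181 without chromosome XII and 0.242 in the authors' tables without it; leaving out single arrays gave 0.244 to 0.378. KNR4 in mid-exponential phase was -6.45 after scaling and -1.89 in the authors' tables. The lists called, 10, 6 and 5, became 0, 0 and 0 with an estimated correlation. With 4 degrees of freedom that test has little power, so it cannot tell whether correlation undoes the calls. In stationary phase 10 lists were called over all tested genes, 12 in the authors' tables and 13 there without chromosome XII, and 1 to 11 with an array left out, the fewest without stationary replicate 1 and the most without replicate 3. For the difference 3 passed without near-identical families, and 3 to 7 with an array left out, the fewest without mid-exponential replicate 1.

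For the single genes named for the largest changes, 294 values kept direction and side of the threshold, 211 kept direction and lost the threshold, and 0 reversed. These genes were picked for passing, those of a phase also for the same sign on 3 arrays. Most alternatives could therefore not reverse them, and the 0 is no sign of stability. Not run were KNR4 in stationary phase and any test of KNR4, for want of ratios, KNR4 without mid-exponential replicate 3, the difference in the authors' tables, which hold each phase alone, and turned signs, since the direction was settled. Dim spots limit the stationary arrays most.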

Other observations

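The tests of dye, plate and copy number on chromosome XII, and the test of a dye bias alike in both phases on the stress genes, were chosen after the results were seen.

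In stationary phase PHO84, the high-affinity phosphate transporter gene, rose by 5.13 ± 0.25 and GIT1, a glycerophosphoinositol transporter gene, by 2.35 ± 0.38 on 2 arrays each, and they were 2 of 17 members of the phosphate list that rose over all genes and 2 adjusted over the list alone (limma; camera adjusted p = 0.698). The phosphate list was not called over all tested genes (adjusted p = 0.086), nor on the t scores of the authors' deposited table (adjusted p = 0.816), so these are 2 single genes. The authors' deposited table called GIT1 (1.46, adjusted p = 0.012) and called neither PHO84 (0.95, adjusted p = 0.078) nor SPS100 (-2.36, adjusted p = 0.130). In mid-exponential phase PHO84 stood at -1.60 ± 1.09 (n = 3, limma adjusted p = 0.195), and its difference between the phases did not pass (adjusted p = 0.060). Among cell cycle and budding genes 5 of 32 rose over all genes and 9 adjusted over the list alone (camera adjusted p = 0.364), among them MCM5 on chromosome XII, SWI4 and ASH1, a daughter-cell repressor gene, at 1.93 ± 0.80 (n = 3). Over all tested genes the cell cycle list was called as higher (adjusted p = 0.0039), and so it was on the t scores of the authors' deposited table (adjusted p = 0.014). It was not called with an estimated correlation (adjusted p = 0.884). The sporulation gene SPS100 fell by 6.72 ± 1.44 on 2 arrays; no other sporulating-cell marker passed over all genes in stationary phase. The haploid-cell markers had none past the threshold over all genes and 2 of 8 fallen adjusted over the list alone.

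Chromosome XII genes stood higher in the mutant on each of the 6 arrays, by 0.73 ± 0.16 (SD, n = 6) against the other chromosomes. Dye bias is argued against by the arrays with the mutant in Cy3, where the lower shift was still 0.579. A plate effect is argued against on plates 11 and 13, where 47 and 59 chromosome XII genes were printed beside genes of other chromosomes. There chromosome XII genes were higher than the others by 0.680 ± 0.150 (SD, n = 6). The remaining chromosome XII genes were not compared within their plates. A candidate explanation is 3 copies of chromosome XII in the mutant against 2 in the wild type, which predicts a log2 ratio of 0.585 along its whole length; 20 of 20 stretches of consecutive genes had means of 0.32 to 0.96, above the highest mean of another chromosome, 0.04. In the authors' deposited table the chromosome XII medians were below 0.585, at 0.34 in mid-exponential and 0.20 in stationary phase. Those medians cover all 551 chromosome XII genes of that table rather than the 359 tested here, so the values are not like for like. A ratio of 2 copies against 1 would predict 1, and the number of copies stays open. DNA content was not analysed here, a lost copy in the wild type cultures stays open too, and whether the change came with the deletion or with the building of the strain was not tested.

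The general stress response list was lower in the stationary mutant on arrays 1 and 3 and not on array 2, where its median was 0.31. A dye bias that acts alike in both phases is argued against: in mid-exponential phase the Cy3 array differed from the mean of the others by -0.042, in stationary phase by 1.27. A dye bias limited to the stationary arrays and a difference between cultures cannot be told apart, since a single stationary array has the mutant in Cy3 and, per the labels, it is also the array whose mutant and wild type came from different fermentation sets. Dim spots might contribute as well; over the brighter members the mean of the array medians was -0.57 ± 0.68 (SD, n = 3), a spread too wide to decide.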
